A study of Mus musculus with 71 samples.

How the data were processed

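The series holds ATAC-seq libraries from mouse embryonic stem cells differentiated to ventral spinal cord progenitors, collected on days 5, 7, 9 and 11 and sorted into p0-p1, p2 and pMN after fixation and intracellular staining. There were 71 libraries in 26 groups of genotype, day, population and NFIA fraction, 7 groups of 2 and 19 groups of 3, and no library was left without a group. Libraries were grouped by their labels: genotype, day, NFIA fraction and replicate number stand in the titles, and populations carry the names of the cell population label, p0-p1 where the title has p1 and pMN where it has pM.

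The authors deposited 1 table of signal values, which are read counts per consensus interval divided by 1 size factor per library. The genome build was mm10 per the labels; the aligner, peak caller and counting tool and their versions were not given in the sources used here. In each column the values were whole multiples of 1 step, and dividing by that step returned whole numbers within a tolerance of 0.01 for 100% of the values. The steps matched median-of-ratios size factors computed from the recovered reads, with a ratio of 1 in all libraries. In 2 libraries, MUT D11 p2 replicate 1 and WT D9 pMN NFIAn replicate 2, the step lay too near 1 to tell a scaled from an unscaled column by this test alone, and they were used in the same way. Recovered reads per library ranged from 20034731 to 31315134, with a median of 24375871. The median over intervals of the mean value was 31.8, at which counting error alone is 17.6%. ATAC-seq reads are not all independent molecules, so limits drawn from counts cover counting error only.

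The table numbers its intervals and gives neither positions nor gene names, so no gene annotation could be joined to it. Gene lists, motif searches and gene-based naming were therefore not analysed here.

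Values were analysed as log2(value + 5) with limma 3.58.1 in R 4.3.3, as 1 fit of 26 group means to all libraries with 45 residual degrees of freedom and a mean-variance trend. Intervals with a value of at least 10 in at least 2 libraries were tested, which kept 155734 of 155738. An interval was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. Comparisons of 3 populations used limma's moderated F-test with a range of the fitted means of at least 1. The 27 comparisons, the threshold, the rule for named intervals and the alternatives were fixed before the data were examined, except where an alternative or a test is said to have been added. The rule named at most 2 intervals up and 2 down per main comparison, those with the largest change among called intervals whose mean was at or above the median and whose libraries did not overlap between the groups within any population. Recovery was tried on simulated negative binomial counts with the mean level and pooled spread of each interval, for 3 of the comparisons. In intervals at or above the median level, 88% to 98% of 3-fold changes and 100% of 6-fold changes were called, with 4 to 12 calls among unchanged intervals. The simulated libraries were independent, had the same spread in all groups and few changed intervals. These rates therefore do not cover correlated replicates or groups that vary more.

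Principal components were computed on the same log2 values. Expected overlaps assume that lists are independent given the number of intervals tested. Root mean square differences between group means had the replicate variance subtracted. Figures were drawn with matplotlib 3.10.9.

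The other settings tried were pseudocounts of 1 and 20, no filter, quantile normalization, equal library totals, a fit of only the groups compared, library quality weights, the replicate number as a block across all libraries or within genotype, and leaving out each library in turn. Added after the data were seen were edgeR 4.0.16 on the recovered reads, a minimum mean value of 30, leaving out intervals in blocks that shift between the genotypes, and leaving out the libraries whose values go against their labels. Replicates in groups that share a number had a mean residual correlation of 0.22 within a genotype and day, and -0.117 for other numbers. Deviations from a group mean sum to 0, so the negative value largely follows from the positive one and is not a separate comparison. The block across all libraries was also used in the comparisons whose numbers paired the libraries. It gave 24074 intervals for WT populations on day 5 and 18759 on day 7. It gave 5925 for the NFIA fractions of p2 and 12067 for MUT against WT in p0-p1 on day 11. This block shares 1 effect per number over all days and both genotypes, so pairing within a day was not modelled by it. Between days 5 and 11, libraries of 1 population that share a number had mean residual correlations near 0. They were 0.0097 in p0-p1, 0.001 in p2 and 0.023 in pMN for WT, and -0.016, -0.0087 and -0.036 for MUT.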

Results

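Chromatin accessibility was measured in 71 libraries from mouse embryonic stem cells that were differentiated in culture towards ventral spinal cord progenitors. The assay, CaTS-ATAC, is ATAC-seq on cells that were fixed, stained inside the cell for marker proteins and sorted, so that each library holds 1 progenitor population. The populations were p0-p1, the most dorsal of the sorted domains, p2, and pMN, the domain that gives rise to motor neurons. Cells were collected on days 5, 7, 9 and 11 from 2 genotypes, WT and MUT, and the labels do not name the mutated gene. Library titles also carry NFIAn or NFIAp, read here as fractions sorted without and with the protein NFIA, a transcription factor known from the switch of neural progenitors towards glial fates.

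There were 38 WT and 33 MUT libraries in 26 groups of 2 or 3. All MUT groups were NFIAn. WT was NFIAn on days 5 and 7, was split into both fractions on day 9 for p2 and pMN, and was NFIAp on day 11. Day and NFIA fraction therefore change together between the ends of the WT course, and genotype and NFIA fraction change together on day 11. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Tests over the mean of the populations treat all libraries as independent. Within a genotype and day, libraries of different populations or fractions that share a replicate number had correlated residuals (mean r 0.22), so these tests may understate the spread. The authors' table gives normalised read counts in 155738 numbered intervals, and 155734 were tested. Each library had between 20034731 and 31315134 reads in the intervals, as recovered from the table. The intervals carry numbers without positions or gene names, so they are reported by number and in groups.

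Day of differentiation was the main axis of the data. The first principal component held 48.3% of the variance and ordered the groups by day in each population and genotype, from -251.73 ± 6.18 (SD, n = 3) in MUT p0-p1 on day 5 to 348.95 ± 19.65 (SD, n = 3) in WT pMN on day 11. The third component held 7.26% and separated p0-p1, p2 and pMN within each day. Over the 32 WT libraries of the NFIAn fractions up to day 9 and of day 11, day accounted for 69.95% of the sum of squares, population for 9.86%, their interaction for 9.23% and differences between replicates for 11.0%. On the third component 1 library lay among another population. The library labelled WT D9 p2 NFIAp replicate 2 had a third-component score of 76.70, beside the pMN groups of that day, while replicates 1 and 3 scored -6.79 and -12.17. WT D7 p2 replicate 2 kept its place by population but differed from its replicates in other measures. The top 1% of its intervals held 15.8% of the signal, against 17.99% and 18.1%, and its normalised total was 22551700, against 27006700 and 24892500.

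**Figure D1:**
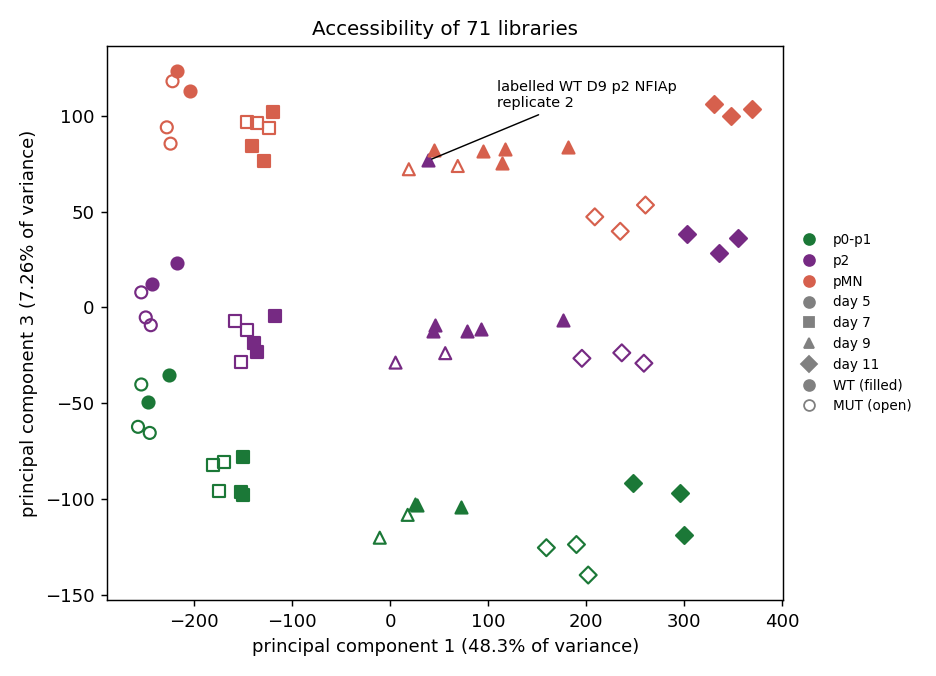
Each point is 1 of the 71 libraries, placed by its scores on principal components 1 and 3 of log2(normalised reads + 5), in arbitrary units; colour gives the population, shape the day, and filled or open symbols WT or MUT. Days run from left to right and populations from bottom to top, and the library labelled WT D9 p2 NFIAp replicate 2 (76.70 on the vertical axis) lies among the pMN libraries.

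The time course asks how accessibility changes as progenitors age, and whether the populations change together. In WT, 42422 intervals rose and 28010 fell in p0-p1 between days 5 and 11. In p2, 40053 rose and 29500 fell, and in pMN 38088 rose and 33903 fell (limma, Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1 on the log2 scale). Of the 56258 intervals that rose in any population, 24981 rose in all 3, against 2668 for independent lists. Of the 44653 that fell in any, 18024 fell in all 3, against 1155 for independent lists. Only 1782 intervals rose in one population and fell in another. With quantile normalization the share of calls that rose in p0-p1 was 48.96%, against 60.2% with the deposited scaling, so the balance of gains and losses depends on the scaling.

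Intervals chosen in WT p0-p1 alone changed in the same direction in libraries that took no part in the choice. Those that rose in p0-p1 had a median change of 1.65 (log2; interquartile range 0.88 to 2.51) in WT p2 and 1.49 (0.52 to 2.51) in WT pMN, with 93.7% and 86.1% of them above 0. Those that fell had medians of -1.53 in WT p2 and -1.38 in WT pMN, and 98.9% and 97.5% were below 0. The populations were not identical in this respect, since the change from day 5 to day 11 differed among them in 37213 intervals (limma F-test of the difference, largest minus smallest change at least 1).

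**Figure D2:**
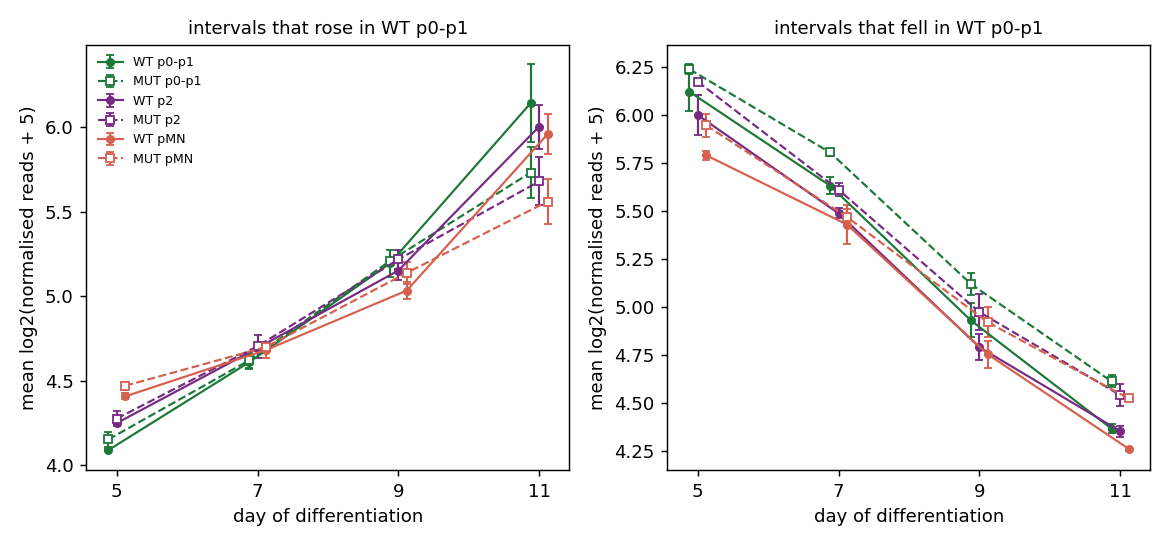
Mean log2(normalised reads + 5) over the intervals that rose (left) or fell (right) in WT p0-p1 between days 5 and 11, by day; points are group means, bars are SDs of 2 or 3 libraries, solid lines WT and dashed lines MUT, with the NFIAn fraction shown on day 9. The intervals were chosen in WT p0-p1, whose own ends are therefore not independent, and the choice leaves out changes found only in MUT. On day 11 the left panel shows WT pMN at 5.96 ± 0.12 and MUT pMN at 5.56 ± 0.13 (SD, n = 3).

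By the rule for named intervals, Interval_40963 and Interval_52003 rose the most over the mean of the populations. Interval_40963 had 8.24 ± 1.41 normalised reads (SD, n = 6) in WT on day 5 and 1659 ± 472 (SD, n = 9) on day 11, a log2 change of 6.92 (SE 0.19). Interval_52003 went from 3.04 ± 0.71 (SD, n = 6) to 972 ± 347 (SD, n = 9). Interval_127406 fell from 1289 ± 202 (SD, n = 6) to 10.5 ± 7.01 (SD, n = 9), and Interval_150095 from 594 ± 56.5 (SD, n = 6) to 4.01 ± 1.93 (SD, n = 9). Each n counts libraries of all populations together, so the SDs include differences between populations and n is not a number of replicates.

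The WT course was not even in time. Averaged over the populations, 18353 intervals changed from day 5 to day 7 (11944 rose, 6409 fell), 13439 from day 7 to the day 9 NFIAn fraction (4868 rose, 8571 fell) and 32097 from that fraction to day 11 (23883 rose, 8214 fell). In the last step 74.4% of the calls rose with the deposited scaling and 60.7% with quantile normalization. The last step also passes from the NFIAn to the NFIAp fraction. The day 7 groups include the library labelled WT D7 pMN replicate 3, whose reads go against its genotype label as described with the comparison of the genotypes, and without it and its MUT counterpart the first 2 steps gave 18364 and 12985 intervals.

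The MUT cells also changed over time. Between days 5 and 11, 37560 intervals rose and 27034 fell in MUT p0-p1, 34873 rose and 27841 fell in p2, and 30730 rose and 30359 fell in pMN, all in NFIAn fractions. Of the 39560 intervals that rose in WT over the mean of the populations, 66.9% also rose in MUT, and of the 28885 that fell in WT, 79.6% also fell in MUT. From the other side, 26449 of the 32757 that rose in MUT also rose in WT, and 23001 of the 26704 that fell in MUT also fell in WT. The intervals chosen in WT p0-p1 can be followed in populations that were not used to choose them. The choice was still made in WT and leaves out changes found only in MUT, so a weaker median in MUT is partly built in. Those that rose had medians of 1.33 in MUT p2 and 1.01 in MUT pMN, against 1.65 and 1.49 in the same populations of WT. Those that fell had medians of -1.503 in MUT p2 and -1.28 in MUT pMN, against -1.53 and -1.38 in WT.

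The populations were compared within each day. In WT, 23433 intervals differed among p0-p1, p2 and pMN on day 5, 18692 on day 7, 19112 in the day 9 NFIAn fractions and 30589 on day 11 (limma F-test, adjusted p under 0.05 and a range of at least 1). On day 5, 69.0% of them were highest in pMN and 4.40% in p2. On day 11, 48.8% were highest in p0-p1, 31.0% in pMN and 20.3% in p2. By the rule for named intervals, Interval_143708 had 414.6 ± 275.2 normalised reads in WT p0-p1 (SD, n = 3) on day 11 and 9.29 ± 4.67 in p2 and pMN together (SD, n = 6). In MUT on day 11, 23663 intervals differed and 51.4% of them were highest in p0-p1.

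The intervals that set the populations apart were partly replaced over time. Of the intervals called on day 5, 43.3% were also called on day 7 and 25.1% on day 11, when 5883 were shared against 4603 for independent lists. The same population was highest in 78.9% of those shared by days 5 and 7 and in 50.0% of those shared by days 5 and 11. Between the day 9 NFIAn fractions and day 11, 9789 intervals were shared against 3754 for independent lists, with the same population highest in 82.5%. On day 11, WT and MUT shared 15707 population-dependent intervals against 4648 for independent lists, with the same population highest in 89.6%. The root mean square log2 difference between p0-p1 and p2, with replicate variance removed, was 0.31 on day 5 and 0.62 on day 11 in WT, and 0.34 and 0.46 in MUT. Between p2 and pMN it was 0.43 on day 5 and 0.36 on day 11 in WT, and 0.46 and 0.34 in MUT. Between p0-p1 and pMN it was 0.71 and 0.72 in WT, and 0.73 and 0.60 in MUT.

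**Figure D3:**
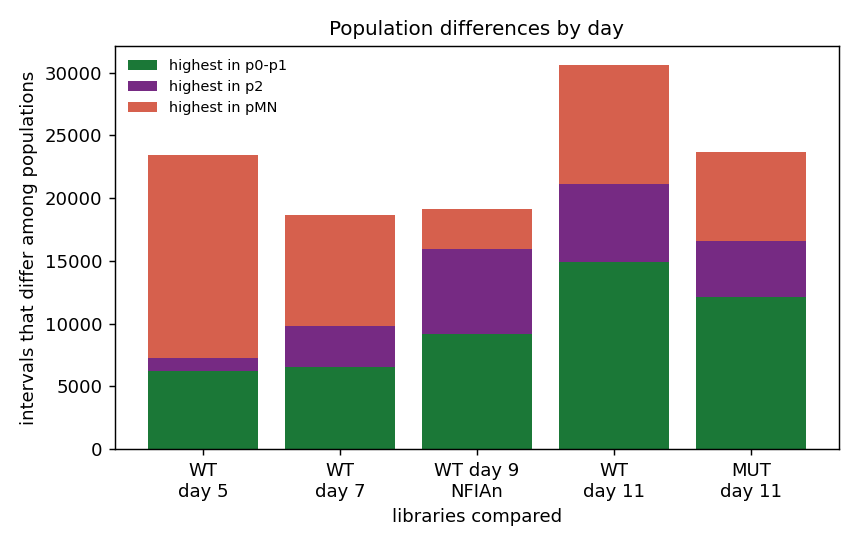
Bars give the number of intervals that differed among p0-p1, p2 and pMN on each day in WT and on day 11 in MUT, divided by the population in which the interval was highest. The count was 23433 in WT on day 5, mostly highest in pMN, and 30589 on day 11, most often highest in p0-p1.

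Day 9 is the only day with both NFIA fractions of WT p2 and pMN. In p2, 5839 intervals differed, with 1781 higher and 4058 lower in the NFIAp fraction. This comparison contains the library labelled WT D9 p2 NFIAp replicate 2, which lay with pMN. Without it 10380 intervals differed, 5664 higher and 4716 lower, and with all libraries edgeR called 9896, 4893 higher and 5003 lower. A fit of only these groups called 1779, 60 higher and 1719 lower, so the count and its balance depend on that library and on the method. By the rule for named intervals, Interval_121864 rose the most, from 4.14 ± 3.60 to 34.1 ± 12.1 normalised reads (SD, n = 3 each), and Interval_123167 fell the most, from 111 ± 27.2 to 13.0 ± 13.1 (SD, n = 3 each).

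In pMN, 19 intervals were higher in the NFIAp fraction and 0 were lower by limma. An unadjusted p under 0.05 was found for 15219, or 9.77% of the intervals, where a share of 0.05 would arise without any difference. edgeR called 18, all higher. The count went to 141 without WT D9 pMN NFIAn replicate 1, 0 without NFIAn replicate 2 (9730 at an unadjusted p under 0.05), 1 without NFIAp replicate 1, 41 without NFIAp replicate 2 and 106 without NFIAp replicate 3, so no number of NFIA-dependent intervals can be given for pMN. The NFIAp minus NFIAn difference itself differed between p2 and pMN in 2431 intervals, by a test added after the data were seen. In p2 it was larger in 98 and smaller or more negative in 2333, so this split gives the direction and not the strength. With the 3 doubted libraries left out it was larger in 440 and smaller or more negative in 2085. The number of larger ones therefore depends on these libraries, and the test rests on the same pMN libraries.

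The changes between the fractions ran with the WT change from day 7 to day 11, measured in other libraries. That change also passes from the NFIAn to the NFIAp fraction, so day and fraction cannot be told apart in it. Across intervals, which are not independent replicates, the NFIAp minus NFIAn difference correlated with the change from day 7 to day 11 at r = 0.39 in p2 and 0.50 in pMN, and at 0.50 in p2 with the doubted libraries left out. With all libraries, the intervals higher in NFIAp p2 had a median change of 1.70 from day 7 to day 11, and those lower had a median of -0.61. With the doubted libraries left out the medians were 1.90 and -0.81. The fractions of p2 and pMN agreed less, as their differences correlated at r = 0.26 with all libraries. In pMN the intervals higher in NFIAp p2 had a median difference of 0.43, and those lower a median of 0.01.

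MUT was compared with WT on each day. Over the mean of the populations, 181 intervals differed on day 5 (150 higher and 31 lower in MUT), 44 on day 7 (31 and 13, with 2 libraries whose genotype labels are in doubt), 1025 in the day 9 NFIAn fractions (594 and 431) and 12770 on day 11 (1668 and 11102). On day 11 the lower intervals numbered 10226 in p0-p1, 12228 in p2 and 13174 in pMN, and the higher ones 1832, 3958 and 5169. Of the 16996 intervals lower in any population, 7321 (43.1%) were lower in all 3, against 68 for independent lists. Of the 8464 higher in any, only 374 (4.42%) were higher in all 3, against 2 for independent lists. On day 11 MUT is NFIAn and WT is NFIAp, so this difference cannot be assigned to genotype alone. The day 5 count was 825 with a pseudocount of 1, 844 with the replicate block within genotype and 1033 by edgeR, and the day 7 count was 229, 212 and 260, so the small early counts depend on the method. The day 9 count was 2964 with a pseudocount of 1 and 3425 by edgeR.

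The share of higher calls depended on the scaling. On day 5 it was 82.9% as deposited and 62.7% with quantile normalization, and on day 7 it was 70.5% and 52.5%. On day 9 it was 58.0% as deposited, 32.5% with quantile normalization and 72.3% with equal totals, so no direction can be given for that day. On day 11 it was 13.1% as deposited and 27.99% with equal totals. Within populations on day 11, equal totals moved it from 15.2% to 26.7% in p0-p1, from 24.5% to 43.1% in p2 and from 28.2% to 44.7% in pMN, and lower calls remained the larger part. By edgeR 7121 were higher and 13396 lower over the mean of the populations on day 11, 4704 and 12927 in p0-p1, 8766 and 13814 in p2, and 10444 and 14856 in pMN, so lower calls were again more numerous but the number of higher calls depends on the method. Equal totals moved the median change of all intervals on day 11 from 0.05 to 0.17.

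The intervals lower in MUT on day 11 were mostly ones that rose in WT by day 11. Of the 11102, 90.1% also rose in WT from day 5 to day 11, a share that rests partly on the same WT libraries. Among all 155734 tested intervals, 39560 rose in WT. Their median change from day 5 in WT was -0.02 on day 7, 0.20 in the day 9 NFIAn fractions and 2.17 on day 11. In MUT the medians were -0.05, 0.07 and 0.32. The day 11 values are those used to choose the intervals. From day 9 to day 11 the WT values also pass from the NFIAn to the NFIAp fraction. A late rise therefore cannot be told from a difference between the fractions. The change from day 5 to day 11 itself differed between the genotypes in 13294 intervals, smaller or more negative in MUT in 11987 and larger in 1307.

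**Figure D4:**
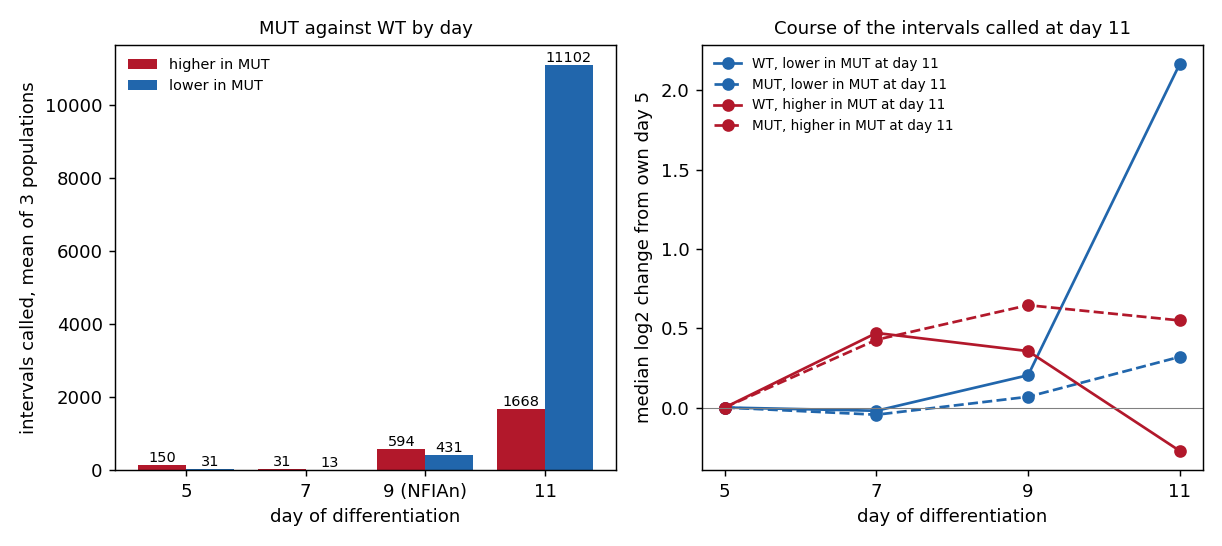
Left, the number of intervals higher (red) or lower (blue) in MUT than in WT by day, over the mean of 3 populations, where day 7 includes the 2 libraries labelled pMN replicate 3 and the day 9 direction flips with quantile normalization (32.5% higher). Right, the median log2 change from each genotype's own day 5 for the 11102 intervals lower and the 1668 higher in MUT on day 11, with solid lines for WT and dashed lines for MUT and the NFIAn fraction on day 9; the lower set reached 2.17 in WT and 0.32 in MUT on day 11, where it was chosen.

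With replicate variance removed, the group means of MUT and WT differed by a root mean square of 0.17 in p0-p1, 0.16 in p2 and 0.15 in pMN on day 5 (log2). The values were 0.20, 0.18 and 0 on day 7, where the pMN groups hold the 2 libraries in doubt and differed by no more than the replicate variance, 0.21, 0.24 and 0.31 in the day 9 NFIAn fractions and 0.55, 0.68 and 0.72 on day 11. MUT on day 11 was about as far from the WT NFIAn fraction of day 9, at 0.54 in p0-p1, 0.66 in p2 and 0.67 in pMN. From the WT NFIAp fraction of day 9 it was 0.58 in p2, with the library that lay with pMN included, and 0.52 in pMN. Among named intervals on day 11, Interval_53741 had 652 ± 261 normalised reads in WT and 9.58 ± 4.26 in MUT (SD, n = 9 each), and Interval_118950 had 741 ± 254 in WT and 11.9 ± 3.35 in MUT (SD, n = 9 each). Interval_112350 had 4.22 ± 2.39 in WT and 127 ± 33.5 in MUT (SD, n = 9 each), and Interval_30108 had 30.8 ± 8.69 in WT and 166 ± 35.8 in MUT (SD, n = 9 each). These n pool the libraries of all populations, so the SDs include population differences and n is not a number of replicates.

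A run of 5 intervals with consecutive numbers, Interval_143053 to Interval_143057, separated the genotypes on every day. It was picked after its values were seen. The run held 0 or 1 reads, 4 in total, in 32 of the 33 libraries labelled MUT and 148 to 519 reads in 37 of the 38 labelled WT. The library labelled MUT D7 pMN replicate 3 had 213 reads in the run, and the library labelled WT D7 pMN replicate 3 had 0. A count of 0 allows up to 3 reads, which is 1.35% of the mean of the other 37 WT libraries and covers counting error only. Interval_112350 showed the mirror image, with 73 to 199 reads in the other MUT libraries, 2 to 14 in the other WT libraries, 8 in the library labelled MUT D7 pMN replicate 3 and 166 in the library labelled WT D7 pMN replicate 3. In both measures each of the 2 libraries lay with the genotype opposite to its label, and the day 7 count of 44 was 188 without them (144 higher and 44 lower in MUT). It was 93 without the library labelled MUT D7 pMN replicate 3 alone, 86 without the library labelled WT D7 pMN replicate 3, 27 without MUT D7 pMN replicate 2 and 28 without WT D7 pMN replicate 1. The day 9 count of 1025 was 1740 without WT D9 pMN NFIAn replicate 2.

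**Figure D5:**
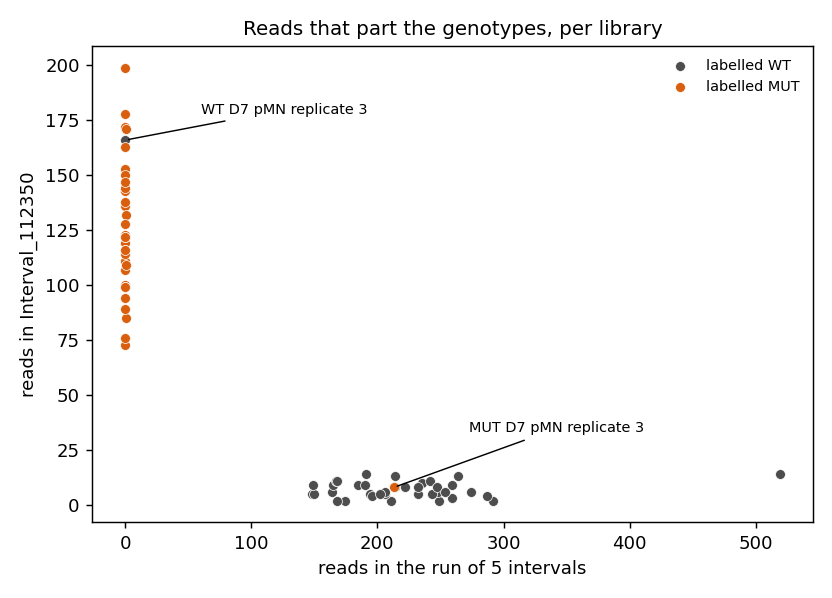
Each point is 1 library, with the reads in the run of 5 intervals on the horizontal axis and the reads in Interval_112350 on the vertical axis, coloured by the labelled genotype. MUT libraries lie at 0 or 1 reads in the run and WT libraries at 148 to 519, except the 2 libraries labelled D7 pMN replicate 3, which lie with the other genotype.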

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

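The tests of shifted blocks and of the NFIA-positive fraction were chosen after the result was seen. So were the comparison of the genotypes within the day 9 NFIAn fractions and all tests on libraries that lie apart from their labels. The interaction of NFIA fraction with population was also chosen after the result was seen. The tests of scaling, of single libraries and of other splits were planned as settings. Their predictions were written only after summaries of the data had been made, so they cannot be taken as written before the result. The change from day 5 to day 11 differed between MUT and WT in 13294 intervals, by a test of the difference itself. It differed among the 3 WT populations in 37213 intervals by the corresponding F-test. The NFIAp minus NFIAn difference on day 9 differed between p2 and pMN in 2431 intervals. In p2 it was larger in 98 and smaller or more negative in 2333. This comparison includes the library labelled WT D9 p2 NFIAp replicate 2, and without the 3 doubted libraries 440 were larger and 2085 smaller or more negative.

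Most intervals that differed between the genotypes on day 11 were lower in MUT (11102 of 12770). After quantile normalization 92.04% of the lower intervals were still called lower, and with any 1 library left out the count of all calls stayed at 97.31% or more of 12770. Neither quantile normalization nor leaving out 1 library therefore removed most of the calls. The first test follows only intervals already called lower, and equal totals raised the share of higher calls, so the size of the imbalance depends on the scaling. The blocks of intervals that shift between the genotypes on every day held 18.01% of the lower intervals and 16.06% of all tested ones, which argues against them as the source. Relative to intervals matched on level and WT time change, the lower intervals differed between the day 9 NFIAp and NFIAn fractions by 0.02568 (log2; 0.07 in p2 and -0.02 in pMN; two-sided exact permutation p = 0.61 over 200 free arrangements, and 0.487 over 80 that exchange p2 libraries only within replicate numbers), and all 3 p2 pairs, 1 of them with the doubted library, were above 0 (exact p = 0.25, the smallest that 8 arrangements can give). Within the day 9 NFIAn fractions, MUT minus WT was -0.18 over the populations (-0.05 in p0-p1, -0.18 in p2 and -0.29 in pMN; -0.30 for MUT replicate 1 and -0.05 for replicate 2, each against all WT), with a two-sided exact permutation p of 0.0267 over 600 free arrangements but 0.3 over the 10 that move libraries of a number together, which cannot go below 0.1, so genotype and sorted fraction cannot be told apart on day 11, where WT is NFIAp and MUT is NFIAn.

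The library labelled WT D9 p2 NFIAp replicate 2 lay with pMN. On a score set to 0 at the other labelled p2 libraries and 1 at the pMN libraries of WT day 9, it scored 0.9305, inside the range of the 5 pMN libraries (0.914 to 1.08) and outside that of the other 5 p2 libraries (-0.194 to 0.264). A fairly even mixture of both populations would have scored between these ranges, but a mixture of mostly pMN cells could score the same. Low depth is argued against by its 23.72 M reads, within the range of the other WT day 9 libraries (22.2 to 29.1). Its quality weight was 0.32, against 0.49 and 0.63 in replicates 1 and 3. This weight measures distance from the group, so it cannot tell a poor library from a wrong label. A pMN library under a p2 label is a candidate explanation; no WT day 9 pMN library was out of place, so no partner for an exchange was found among them. No biological explanation was tested.

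The libraries labelled WT D7 pMN replicate 3 and MUT D7 pMN replicate 3 carried the values of the opposite genotype. On a score over the shifted blocks, set to 0 at the other WT and 1 at the other MUT day 7 libraries, the library labelled WT scored 1.056 and the library labelled MUT 0.108, against -0.223 to 0.381 in the other WT and 0.791 to 1.13 in the other MUT libraries. Cells of both genotypes in the library labelled WT are argued against by its 0 reads, 0% of the median of 238.5 in the other WT day 7 libraries, in the run of intervals that MUT lacks. Genotype labels exchanged between these 2 libraries may therefore account for the values, and no biological explanation was tested.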

How the results depend on the processing

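The tests with edgeR, with a minimum mean of 30, without shifted blocks and without doubted libraries were chosen after the data were seen, and all other alternatives were planned. Across the 27 results, all counts stayed within 1.5 times their value without the filter (which removed 4 intervals and so tests little), with quantile normalization, with equal totals and without the intervals in shifted blocks. Quantile normalization and equal totals moved the balance of higher and lower calls where the report gives it. Under equal totals the median change of all intervals in MUT against WT on day 11 was 0.17 over the populations, 0.12 in p0-p1, 0.19 in p2 and 0.19 in pMN (log2), and under quantile normalization that of WT day 11 against day 9 was -0.14. Counting error at the median value limits changes in the weaker intervals. The gene lists, the motif searches and their alternatives (nearest start site, estimated correlation, bins of base content and length) were not run, because the intervals carry no positions.

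With a pseudocount of 20, which shrinks changes at low values, 26 results moved by over 1.5 times. WT D11 against D5 gave 42108 in p0-p1, 41561 in p2, 44225 in pMN and 38408 over the mean, and MUT gave 37309, 36490, 35171 and 32091. The WT steps gave 7589 (D7 against D5), 5522 (D9 against D7) and 16825 (D11 against D9). Populations gave 11992 on D5, 7545 on D7, 7169 on D9 and 15156 on D11 in WT, and 9513 on D11 in MUT. NFIA fractions gave 1941 in p2 and 86 in pMN. MUT against WT gave 44 on D5, 12 on D7, 266 on D9 and 6966 on D11, with 5451 in p0-p1, 8569 in p2 and 9857 in pMN, and genotype by time gave 7272. With a pseudocount of 1, WT D7 against D5 gave 28443, D9 against D7 22679, NFIA in pMN 10, and MUT against WT 825 on D5, 229 on D7 and 2964 on D9.

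With a minimum mean of 30, fewer intervals (80567) were tested and 25 counts fell by over 1.5 times. WT D11 against D5 gave 34139 in p0-p1, 34132 in p2, 34817 in pMN and 32930 over the mean, and MUT gave 31911, 31686, 30639 and 29940. The WT steps gave 11038 (D7 against D5) and 16492 (D11 against D9). Populations gave 12733 on D5, 10128 on D7, 9733 on D9 and 13068 on D11 in WT, and 10710 in MUT. NFIA fractions gave 3243 in p2 and 8 in pMN. MUT against WT gave 73 on D5, 29 on D7 and 5352 on D11, with 4554 in p0-p1, 6822 in p2 and 8161 in pMN, genotype by time 5317 and population by time 18336.

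With edgeR, WT D7 against D5 gave 30362, D9 against D7 24834, NFIA in p2 9896, and MUT against WT 1033 on D5, 260 on D7, 3425 on D9 and 20517 on D11; the cause was not tested. With only the groups compared in the fit, limma called 1779 for NFIA in p2 and 0 in pMN. In pMN 17063 (10.96% of the intervals) then had an unadjusted p under 0.05, and edgeR called 18 in the fit of all libraries. Library quality weights gave 68 for MUT against WT on D7. The replicate block gave 288 for NFIA in pMN. The replicate block within genotype gave 411 for NFIA in pMN and 844 on D5 and 212 on D7 for MUT against WT; the cause was not tested. Without the pair of doubted D7 libraries, MUT against WT on D7 gave 188, and without the 3 doubted libraries it gave 188, NFIA in p2 10396 and NFIA in pMN 251.

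With each library of the groups compared left out in turn, the lowest and highest counts were as follows, where an arm left with 1 library is assumed to vary like the other groups. WT D11 against D5 ranged over 69011 to 72662 in p0-p1, 68042 to 71728 in p2, 71078 to 73390 in pMN and 67743 to 69435 over the mean. MUT ranged over 62968 to 66746, 60713 to 65721, 59792 to 63197 and 58651 to 60590. The WT steps ranged over 17589 to 19369, 12634 to 14920 and 30729 to 34204. WT populations ranged over 17019 to 24199 on D5, 18482 to 20125 on D7, 15863 to 20253 on D9 and 29971 to 32320 on D11, and MUT populations over 22611 to 26002. MUT against WT ranged over 166 to 267 on D5 and 12427 to 13377 on D11, with 9652 to 16504 in p0-p1, 16106 to 17971 in p2 and 17563 to 20185 in pMN. Genotype by time ranged over 12843 to 13919 and population by time over 30210 to 37430. NFIA in p2 ranged over 4434 to 10380, the highest without the library labelled WT D9 p2 NFIAp replicate 2. NFIA in pMN ranged over 0 to 141, with 141 without NFIAn replicate 1, 0 by limma without NFIAn replicate 2 (9730 at an unadjusted p under 0.05, 18 by edgeR with all libraries), 1 without NFIAp replicate 1, 41 without NFIAp replicate 2 and 106 without NFIAp replicate 3. MUT against WT on D7 ranged over 27 to 93, with 27 without MUT pMN replicate 2, 93 without the library labelled MUT pMN replicate 3, 28 without WT pMN replicate 1 and 86 without the library labelled WT pMN replicate 3. On D9 it ranged over 770 to 1740, the highest without WT pMN NFIAn replicate 2.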

Other observations

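The block comparisons and the higher set below were chosen after the data were seen, and the splits were planned. The 1668 intervals higher in MUT on day 11 followed another course than the lower ones. Their median change from day 5 was 0.47 on day 7, 0.36 in the day 9 NFIAn fractions and -0.27 on day 11 in WT, and 0.43, 0.65 and 0.55 in MUT, where the day 11 values are those used to choose them. On both day 9 and day 11, 385 intervals were lower in MUT, against 30.7 for independent lists, and 161 were higher in MUT, against 6.36.

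In intervals that rose in WT over the mean of the populations, the median change was 0.24 from day 5 to day 7, 0.43 to the day 9 NFIAn fractions and 1.08 to day 11. In those that fell it was -0.44, -0.64 and -0.54. The sets were chosen on the day 5 and day 11 libraries that enter the first and last steps. The root mean square difference between p0-p1 and pMN in WT was 0.71 on day 5, 0.55 on day 7, 0.49 in the day 9 NFIAn fractions and 0.72 on day 11 (log2).

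In 5 blocks of consecutively numbered intervals the median value of the block, relative to all other intervals, differed between the genotypes in the same direction in 12 of 12 combinations of day and population. The blocks were found from a running median of the MUT minus WT difference in these libraries, so this agreement is partly built in. MUT minus WT was -0.208 in intervals 18582 to 29363, 0.21 in 39613 to 41234, 0.0412 in 66083 to 68128, -0.105 in 117429 to 118538 and -0.204 in 134303 to 143753 (log2, without the libraries labelled D7 pMN replicate 3). Single libraries of the genotypes overlapped in 134303 to 143753 (MUT -0.2325 to 0.1365, WT -0.04171 to 0.2632). They did not overlap in 39613 to 41234 (MUT 0.05924 to 0.1877, WT -0.1852 to 0.01959).

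Other splits of the same libraries into groups of the same sizes were counted for each comparison of at least 3 libraries a side. Of 100 splits drawn, the real one included, 1 gave as many intervals as the real split in each of the following. Except on day 7 for MUT against WT, chance can be excluded only as far as libraries can be exchanged one by one. Libraries of 1 genotype and day that share a replicate number were correlated (mean r 0.22 over 83 pairs, lowest 0.0425), which the splits ignore, and at most 11 other draws parted as many pairs as the real split, too few for a share under 0.05. The real and the highest other count were 68445 and 48580 for WT day 11 against day 5 over the mean, and 59461 and 43792 for MUT. They were 18353 and 8405, 13439 and 9761, and 32097 and 24778 for the successive WT steps. They were 18692 and 14578 for WT populations on day 7, 30589 and 23168 on day 11, and 23663 and 16012 for MUT populations on day 11. For MUT against WT they were 181 and 42 on day 5, 1025 and 517 on day 9, and 12770 and 8563 on day 11, and for genotype by time 13294 and 10107. On day 7 they were 44 and 42, a margin of 2 calls in a comparison that keeps the 2 doubted libraries under their labels and gave 27 without MUT pMN replicate 2, so no statement on chance is drawn from it. For WT populations on day 7, whose numbers pair the libraries, 11 other draws parted all 9 pairs and gave at most 12423. The highest other count can come from a draw close to the real split. For WT day 11 against day 5 that draw exchanged libraries only in pMN, and for MUT against WT on day 11 only in p2. The median count over the other draws was 904 and 3882 for WT populations on days 7 and 11 and 1092 for MUT populations. It was 1 for WT day 7 against day 5 and 0 for the other comparisons in this paragraph.

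With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 with the most intervals in each. The real and the highest other count were 64594 and 1 for MUT day 11 against day 5 in p0-p1, 62714 and 0 in p2, and 61089 and 0 in pMN by limma. They were 5839 and 3268 for the NFIA fractions in p2, where the 3 other splits that part all pairs gave at most 643. For MUT against WT on day 11 they were 12058 and 4003 in p0-p1, 16186 and 0 in p2, and 18343 and 48 in pMN, and in p0-p1 the 3 other splits that part all pairs gave at most 0.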
